A study of Mus musculus with 2 samples.

How the data were processed

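Total RNA from embryonic mouse forebrain was sequenced for 2 genotypes, H2A.Z floxed control and H2A.Z conditional knockout, with 1 labelled sample each. Per the labels' protocols, RNA was extracted with Trizol and TruSeq libraries were made from 2 ug of total RNA. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0, with no roles given, and the build mm9. Gene positions in the deposited table were compared with GENCODE M21 gene models on GRCm38: 15565 of 19720 positions (78.9%) were identical and 99.5% overlapped the same gene. Coordinates are therefore those of the deposited table and are given as GRCm38. The annotation release, the strand setting, the treatment of reads that match several genes and any pooling of animals or libraries are not given in the sources used here.

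Raw read counts per gene, 1 column per genotype, are given per the file headers, and they sum to 8474545 reads in the control and 9028523 in the knockout. The table lists only genes with at least 1 read in either library. The authors also deposited CPM columns, in which each count, with 0 entered as 0.5 read, is divided by a constant per sample. These constants imply totals of 8477573 and 9031286 reads, so 3028 and 2763 reads lie outside the listed genes. The deposited fold column is the ratio of the authors' control CPM to their knockout CPM, and the deposited log2 column is its logarithm, so that positive values are higher in the control. The authors' p-value and adjusted p-value columns come from a test that is not given in the sources used here. Genes marked by the authors as significant all had an adjusted p below 0.05 and at least a 2-fold difference in the deposited table. Of the gene identifiers, 19623 matched a GENCODE M21 symbol and 97 did not.

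With a single count column per genotype, no test between genotypes could be made and no p-value was computed. Counts were scaled by the TMM method in edgeR 4.0.16 (R 4.3.3), and the log2 ratio of knockout to control was taken with a prior of 0.5 read. A gene counted as measured with at least 20 reads in the sum of both libraries and as apart at a ratio of at least 1.5 either way. It was beyond counting error when the exact 95% Clopper-Pearson interval on the split of its reads excluded a ratio of 1. Where a library had 0 reads, the fold is given against a floor of 3 reads in that library. That floor is a TMM-scaled CPM of 0.350 in the control and 0.336 in the knockout. The other library's count is taken as exact, so this fold is not a 95% limit. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. These choices, the 35 gene lists and the rule for named genes were fixed before the data were examined.

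For each gene list, the median log2 ratio of measured members was set against the medians of 10000 random lists of the same size, matched on expression in 20 bins. These numbers describe the 2 libraries and are not p-values. The lists cover H2A.Z machinery, H3K56 acetylation, histones, folate, astrocyte, JAK-STAT, BMP, Notch, radial glia, intermediate progenitor, pan-neuronal, deep-layer, upper-layer, ventral telencephalic, Cajal-Retzius, oligodendrocyte, S phase, G2/M, p53, ribosomal, respiratory chain, mitochondrially encoded, immediate early, heat shock, sex-linked, imprinted and germline, and Polycomb genes. They also cover diencephalic, midbrain and hindbrain markers and 7 kinds of other tissue: choroid plexus, microglia, endothelium, pericytes, meninges, erythroid cells, and eye, pituitary and craniofacial tissue. Annotation terms in the table were ranked by the median of their measured genes, for terms of 15 to 200 genes, and the 5 at each end were described.

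Named genes were H2afz and H2afv, 14 genes that the subject of the study names or that mark its main cell types, the 10 highest and 10 lowest log2 ratios among genes with a symbol and at least 100 reads in the higher library, and up to 4 members furthest from 0 in each list. Values of 2 genes under this rule are not reported here. Genes named outside this rule are Raly, Eif2s2, agouti, Chmp4b, Ahcy, Cdk5rap1, Necab3 and 6430550D23Rik at the agouti locus, Anp32e, Gja1, Pdgfra, Prlr and Crabp2, chosen after their values were seen, and genes of 2 held-out lists, which were written after the patterns were seen but before the values of those genes were.

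The calculation was tested on simulated counts drawn from the means of the 2 libraries, for 14355 genes. Of 100 simulated 2-fold changes 91 were called beyond counting error in the right direction, and of 100 simulated 4-fold changes 97. Of 14160 simulated unchanged genes, 132 (0.932%) were called beyond counting error and 581 (4.10%) were at least 1.5-fold apart, so part of the counts of genes apart comes from counting error alone. Intervals covered the true ratio for 95.8% of genes. Of 200 simulated lists without a shift, 15 lay outside the central 95% of random lists.

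Alternatives were scaling by library total, by median-of-ratios size factors (DESeq2 1.42.0) and by library total without the 50 most-read genes, read minimums of 1 and 100, a fold threshold of 2, a prior of 5 reads, genes with symbols that are not Gm or Rik models, list means in place of medians, lists without their most extreme member, and random lists matched also on genomic span, since the table gives no transcript length. Alternatives that need replicates or normalised values alone were not run.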

Results

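Transcript levels were measured by RNA sequencing in embryonic mouse forebrain from a control and an H2A.Z conditional knockout. H2A.Z is a variant of histone H2A that replaces the canonical histone in some nucleosomes. The series has 2 genotypes on a C57BL/6 background: mice with floxed H2A.Z alleles, taken here as the control, and H2A.Z conditional knockout mice. The title and count column of the control call it WT, whereas its genotype field gives floxed alleles. Tissue is labelled as telencephalic, and the extraction protocol names dissected cerebral cortex. The titles give embryonic day 16, whereas a characteristics field gives embryonic day 12, so the age is uncertain between these. The design text speaks of triplicates, but the deposited table holds 1 count column per genotype. There are therefore no replicates here, and each difference below is between 1 knockout library and 1 control library. The control library had 8474545 reads in genes and the knockout library 9028523. Of 19720 genes listed, 14366 had at least 20 reads in the sum of both libraries and are called measured. Intervals are exact 95% Clopper-Pearson intervals on the split of a gene's reads and cover counting error only. Folds against the floor of 3 reads are not 95% limits, and the exact interval can reach closer to level. The title of the series frames the question as how H2A.Z acts on the proliferation and differentiation of astrocytes through acetylation of histone H3 at lysine 56.

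The targeted gene, H2afz, was lower in the knockout library. H2afz lies on chromosome 3, from 137864487 to 137866922 in GRCm38 coordinates. It had 1152 reads in the control library and 535 in the knockout library, a log2 ratio of -1.16 (interval -1.31 to -1.01), or 2.24-fold lower. Its paralog H2afv, which encodes the closely related second H2A.Z protein, had 1009 and 1095 reads, a log2 ratio of 0.06 (-0.06 to 0.19). The floxed exons are not given in the sources used here, so reads from exons outside the deleted part cannot be separated from reads of intact transcripts. The list of H2A.Z deposition and removal factors, H2afz included, had 18 of 18 members measured, and H2afz was its single member at least 1.5-fold apart. Yeats4, a subunit of the complexes that deposit H2A.Z, had a log2 ratio of 0.26 (0.13 to 0.40), and Anp32e, a chaperone that removes H2A.Z, was at 0.14 (0.05 to 0.23).

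Most of the transcriptome was level between the libraries, and the genes furthest apart included several anatomical groups. Of the 14366 measured genes, 506 were at least 1.5-fold higher in the knockout library and 780 at least 1.5-fold lower. Of these, 290 and 459 were also beyond counting error. Among genes with at least 100 reads in the higher library, the lowest ratios included genes of the choroid plexus and of fibroblast-like meningeal cells, and the highest included genes of the diencephalon and ventral forebrain and a gene model at the agouti locus. On 7 lists of markers of other tissues, 42 of 104 measured genes were at least 1.5-fold lower and 4 higher. On 2 lists of regional markers outside the dorsal cortex, 19 of 42 were higher and 0 lower.

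**Figure D1:**
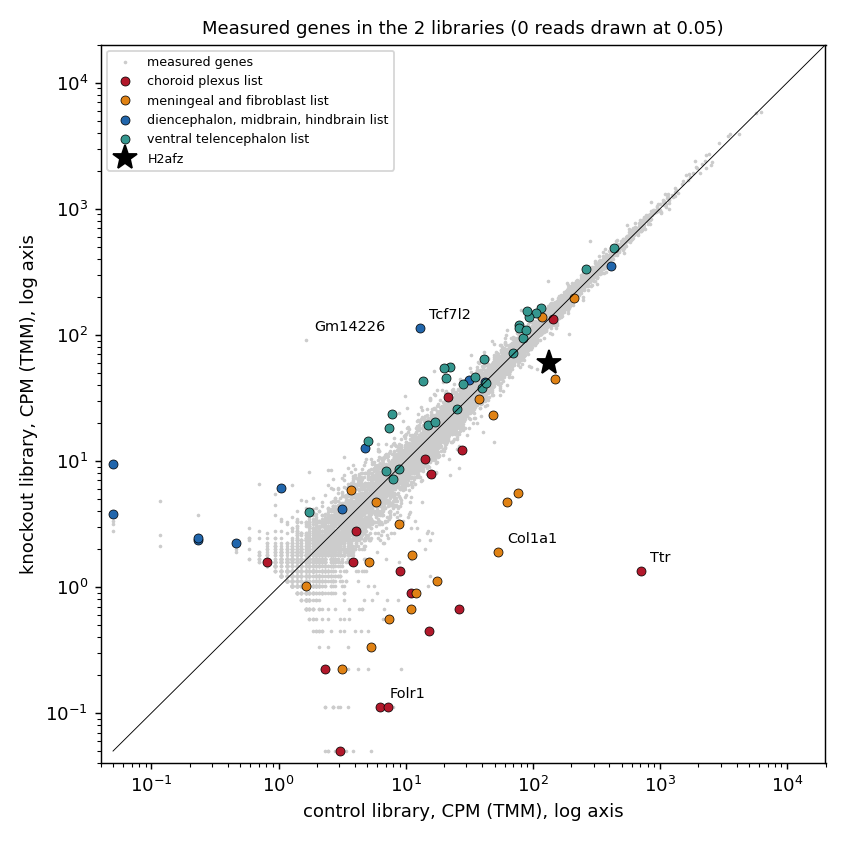
Normalised expression (CPM, TMM scaling) of each measured gene in the control library (x axis, log) and the knockout library (y axis, log), with 4 marker lists and H2afz coloured and genes at 0 reads drawn at 0.05 CPM. Choroid plexus and meningeal genes such as Ttr and Col1a1 lie below the diagonal, and Tcf7l2 and Gm14226 lie above it.

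Choroid plexus genes were lower in the knockout library and, at the main read minimum and prior, had the lowest median of the 35 lists. Ttr, which encodes transthyretin, the thyroid hormone carrier secreted by choroid plexus epithelium, had 6025 reads in the control library and 12 in the knockout library, a log2 ratio of -8.97 (-9.98 to -8.22). Clic6, a chloride intracellular channel family gene, had a log2 ratio of -5.18 (-6.76 to -4.15), and Kcne2, a potassium channel subunit gene, of -4.91 (-6.98 to -3.69). Of 17 measured choroid plexus genes, 12 were at least 1.5-fold lower and 1, the prolactin receptor gene Prlr with 7 and 14 reads, was higher. The list's median log2 ratio was -2.69, also with a gene at 0 reads set to its floor, and 0 of 10000 random lists matched on expression had a lower median. Slc4a5, a bicarbonate transporter gene, had 62 reads in the control library and 1 in the knockout library, a log2 ratio of -5.43 (-11.3 to -3.48). Calml4, a calmodulin-like gene, had 26 and 0 reads and was 9.01-fold lower against the floor of 3 reads. With a minimum of 100 reads the median of this list was -1.199, and the meningeal median of -2.62 was lower. With a prior of 5 reads the 2 medians were -1.87 and -1.98, again with the meningeal list lower.

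Folr1, which encodes folate receptor alpha, was on both the choroid plexus list and the folate list. It lies on chromosome 7, from 101858331 to 101870788, and had 54 reads in the control library and 1 in the knockout library. Its log2 ratio was -5.23 with a wide interval (-11.1 to -3.27). The folate list as a whole, which covers receptors, transporters and enzymes of one-carbon metabolism, was level: 20 of 21 measured members were less than 1.5-fold apart, and Folr1 was the exception. The median was -0.03 (mean -0.28), and 4378 of 10000 random lists had a lower median. Mthfd1l and Aldh1l2, which encode mitochondrial folate enzymes, had log2 ratios of -0.25 (-0.73 to 0.21) and 0.25 (0.09 to 0.41).

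Meningeal and fibroblast genes were lower in the knockout library together with those of the choroid plexus. Of 20 measured members, 15 were at least 1.5-fold lower and 1, the retinoic acid binding protein gene Crabp2 with 32 and 52 reads, was higher. The median log2 ratio was -2.18 and lay below all 10000 random medians; without the most extreme member it was -1.74. Col1a1, a fibrillar collagen gene, had 455 and 17 reads, 27.1-fold lower (17.2 to 48.2). Dcn, the gene of the proteoglycan decorin, was 15.1-fold lower (8.36 to 33.6), and Col6a1, a microfibrillar collagen gene, was 15.2-fold lower (7.29 to 46.0). Slc6a13, a GABA transporter gene of the meninges, had 46 and 3 reads and a log2 ratio of -3.78 (-6.33 to -2.36). The collagen genes Col3a1 and Col1a2, with log2 ratios of -3.76 (-4.22 to -3.36) and -3.72 (-4.23 to -3.29), were also among the 10 lowest of the genes with a symbol and at least 100 reads in the higher library. Aebp1, Ogn and Wfikkn2, which encode secreted or matrix-associated proteins, completed these 10 with log2 ratios of -3.82, -3.66 and -3.59.

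Vascular, blood and immune lists were lower by smaller margins. The endothelial list had a median log2 ratio of -0.31, below all 10000 random medians, and a mean of -0.60, with 4 of 20 members at least 1.5-fold lower. Its member Slco1a4, an organic anion transporter of brain vessels, had 33 and 0 reads and was 11.4-fold lower against the floor of 3 reads. The pericyte list had a median of -0.28, with 4 of 13 members lower and 1 higher, but -0.0058 with a minimum of 100 reads. The erythroid list had a median of -0.28, with 1 of 11 lower. The median of the microglial list was -0.26, inside the central 95% of random lists, but Mrc1, a receptor gene of macrophages at brain borders, was 5.29-fold lower (3.36 to 9.07). The list of eye, pituitary and craniofacial markers had 6 of 29 members measured and a median of -0.51, which turned to 0.0405 with a minimum of 100 reads and was -1.28 as a mean. Krt18, an epithelial keratin gene on that list, had 21 and 0 reads and was 7.28-fold lower against the floor of 3 reads.

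Genes that pattern the diencephalon, midbrain and hindbrain were higher in the knockout library. Tcf7l2, a Wnt pathway transcription factor gene active in the developing thalamus, had 111 reads in the control library and 1017 in the knockout library, 8.78-fold higher (7.24 to 10.8). Shox2, a homeobox gene of the thalamus, had 0 and 85 reads and was 27.2-fold higher against the floor of 3 reads. Irx2, an Iroquois homeobox gene, had 2 and 22 reads, a log2 ratio of 3.12 (1.38 to 6.54). Shox2 and Irx2 reached the read minimum only through their knockout reads. Of the 30 genes on this list of regional markers, 12 were measured, and 8 of these were at least 1.5-fold higher and 0 lower. Its median log2 ratio was 2.30, unchanged with genes at 0 reads set to their floor, and was above all 10000 random medians. With a minimum of 100 reads the median was 0.49.

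Ventral telencephalic genes were higher in the knockout library as well. Of 30 measured members, 11 were at least 1.5-fold higher, 0 were lower, and the median log2 ratio was 0.49, above all 10000 random medians. Isl1, a LIM homeobox gene of striatal and cholinergic neurons, was 3.13-fold higher (2.55 to 3.90), and Dlx6, a homeobox gene of GABAergic progenitors, 2.999-fold higher (2.28 to 4.03). Rxrg, a retinoid receptor gene of the striatum, was 2.86-fold higher (2.03 to 4.18), and Nkx2-1, which specifies the medial ganglionic eminence and hypothalamus, 2.75-fold higher (2.31 to 3.29). Otp, a homeobox gene of hypothalamic neurons, had 41 and 112 reads and was 2.61-fold higher (1.82 to 3.85). Syt13, a synaptotagmin gene, Dlk1, an imprinted Notch-like gene, and Ntng1, which encodes an axonal adhesion protein, were the other named genes of the highest 10 by the same limit, with log2 ratios of 1.73, 1.64 and 1.44.

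The highest ratio among genes with at least 100 reads belonged to Gm14226, a protein-coding gene model on chromosome 2 from 155018266 to 155027104. It had 14 reads in the control library and 817 in the knockout library, 54.3-fold higher (33.3 to 103.1). The values of its neighbours were looked at after this value was seen. The agouti gene, which encodes a melanocortin antagonist that sets coat colour, spans 154791402 to 155051012. It had 0 and 25 reads, 8.01-fold higher against the floor of 3 reads, with an exact interval from 6.05-fold upward. Raly, an RNA-binding protein gene from 154791096 to 154867261, had 1638 and 908 reads, 1.88-fold lower (1.73 to 2.04). Eif2s2, which encodes the beta subunit of translation initiation factor eIF2, lies from 154871410 to 154892935 and had 917 and 474 reads, 2.01-fold lower (1.80 to 2.25). The agouti gene model overlaps Raly, Eif2s2 and Gm14226, so reads in shared stretches cannot be assigned with certainty. Of the other 31 measured genes within 1 Mb, 3 were at least 1.5-fold lower and 0 higher. Cdk5rap1 at -0.64 (-1.16 to -0.14) and Necab3 at -0.61 (-0.99 to -0.24) were lower beyond counting error on the log2 scale, and 6430550D23Rik, with 18 and 10 reads, was not. The nearest measured genes on either side, Chmp4b and Ahcy, were at 0.05 (-0.08 to 0.18) and 0.21 (-0.09 to 0.50).

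**Figure D2:**
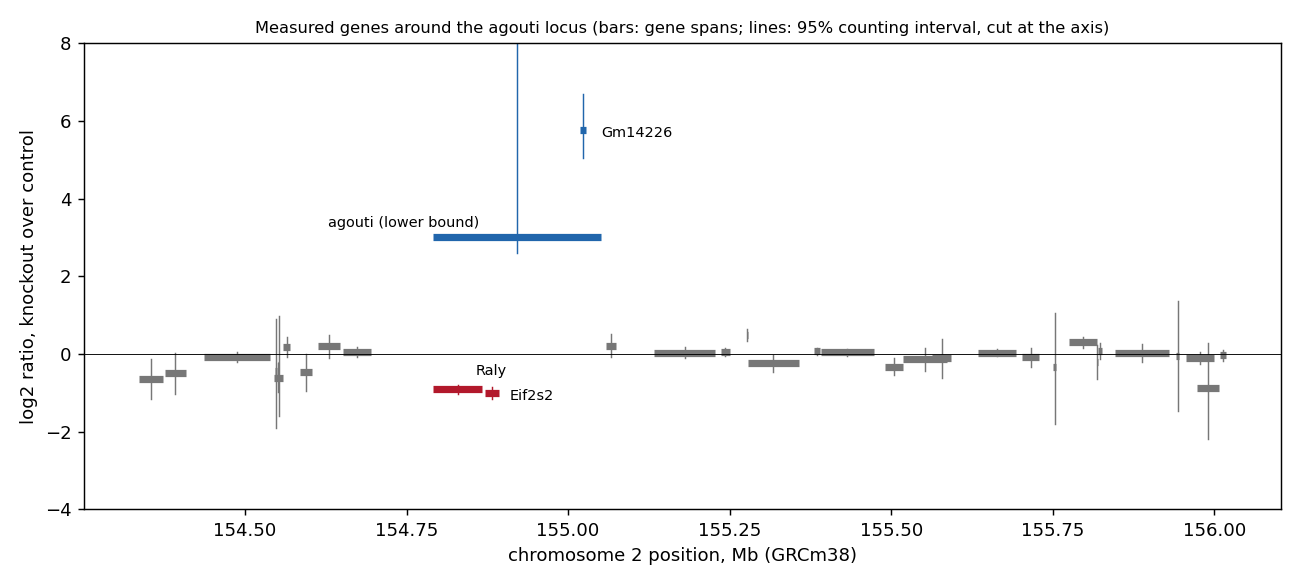
Log2 ratio (knockout over control library, y axis) of measured genes by position on chromosome 2 in Mb (GRCm38, x axis), with horizontal bars for gene spans and vertical lines for the 95% counting interval; agouti, at 0 control reads, is drawn at its lower bound. Raly and Eif2s2 lie near -1, Gm14226 lies at 5.76, and the measured genes other than these and agouti lie between -0.87 and 0.49.

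Genes of the astrocyte lineage, the subject of the study, were slightly lower in the knockout library. Of 24 measured members, 3 were at least 1.5-fold lower and 0 higher, and the median log2 ratio of -0.14 was below all 10000 random medians. The members furthest apart were Cd44, a hyaluronan receptor gene, at -0.84 (-2.02 to 0.23), Clu, which encodes clusterin, at -0.71 (-0.93 to -0.50), Id3, a BMP target, at -0.69 (-1.09 to -0.31), and Apoe, an apolipoprotein gene, at -0.55 (-0.75 to -0.34). Meningeal, vascular or immune cells also express these 4 genes. The mean of the list was -0.20, and without these 4 and Gja1, a reduced list chosen after seeing the data, the median was -0.0817. Mature astrocyte markers were near the limit of detection: Gfap, the astrocyte intermediate filament gene, had 9 and 5 reads, S100b, a calcium-binding protein gene, 1 and 2, and Aqp4, the water channel gene, 10 and 6. At this depth no difference was detectable for these 3 genes. Aldh1l1, a folate enzyme used as an astrocyte marker, had 217 and 218 reads, a log2 ratio of -0.05 (-0.33 to 0.23). Slc1a3, the glial glutamate transporter gene, was at -0.16 (-0.27 to -0.06), and Nfia, a transcription factor gene of the gliogenic switch, at -0.24 (-0.33 to -0.16). Slc1a3 is also on the radial glia list, so the astrocyte list does not measure astrocytes alone.

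Signalling and chromatin lists tied to the study's question had medians inside the range of random lists. The JAK-STAT list had a median log2 ratio of 0.03, with 1 of 20 measured members, the interleukin receptor gene Il6ra with 15 and 10 reads, at least 1.5-fold lower. Stat3, the transcription factor of that pathway, had 376 and 446 reads, a log2 ratio of 0.19 (-0.01 to 0.39). The list of H3K56 acetylation enzymes and histone chaperones had 0 of 15 members at least 1.5-fold apart and a median of 0.02. Asf1a, the histone chaperone needed for H3K56 acetylation, had 342 and 376 reads, a log2 ratio of 0.08 (-0.13 to 0.30), and Sirt6, a deacetylase of this mark, was at -0.31 (-0.54 to -0.09). Medians of the JAK-STAT, H3K56 and H2A.Z machinery lists changed sign when scaled by library total. BMP pathway genes had a median of -0.07, inside the range of random lists, and a mean of -0.41. Of 20 measured members, 5 were at least 1.5-fold lower, all 5 beyond counting error, and 1 was higher. The lower ones included the homeobox gene Msx1, 8.52-fold (4.14 to 23.5), and the ligand gene Bmp6, 5.30-fold (2.69 to 12.9), both of which choroid plexus or meninges also express. The Notch list had a median of -0.06, with Hey2, a Notch target gene, at -0.67 (-1.32 to -0.06).

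Neural progenitor and neuronal lists shifted by small amounts in opposite directions. Radial glia genes had a median log2 ratio of -0.07, with 3 of 10000 random medians lower and 0 of 30 members at least 1.5-fold apart. Pax6, a transcription factor gene of dorsal progenitors, was at -0.20 (-0.33 to -0.07), whereas Sox1 and Sox2, progenitor factors also active outside the cortex, were at 0.38 (0.26 to 0.50) and 0.30 (0.19 to 0.41). Intermediate progenitor genes had a median of -0.07, and their marker Eomes was at -0.25 (-0.33 to -0.16). Pan-neuronal genes had a median of 0.18, above all 10000 random medians, with 19 of 20 above 0. Nefl, a neurofilament gene, was 2.17-fold higher (1.80 to 2.62), and Tubb3, the neuronal tubulin gene, was at 0.20 (0.17 to 0.23). Deep-layer and upper-layer neuron lists had medians of 0.08 and 0.06, inside the range of random lists. Foxp2, a deep-layer gene also active in striatum and thalamus, was 1.87-fold higher (1.66 to 2.12). Cajal-Retzius genes had a median of 0.08, with 0 of 10 at least 1.5-fold apart.

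Oligodendrocyte lineage genes had a median log2 ratio of 0.26, above all 10000 random medians, but a mean of 0.0731, with 3 of 16 at least 1.5-fold higher and 2 lower. Nkx2-2, a homeobox gene of ventral progenitors, was 8.67-fold higher (4.02 to 26.4), and Olig2, the lineage's transcription factor gene, was at 0.44 (0.13 to 0.75). Cldn11, a tight junction gene, had 79 and 2 reads, a log2 ratio of -5.04 (-8.43 to -3.46). Cldn11 is also expressed in meninges. The other lower member was Pdgfra, a receptor gene of oligodendrocyte precursors and of fibroblasts, at -0.71 (-1.05 to -0.39).

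Proliferation and stress lists were level between the libraries. S phase and G2/M lists had medians of 0.01 and 0.02, each with 30 measured members, of which 1, the flap endonuclease gene Fen1 with 15 and 31 reads, was at least 1.5-fold apart. Both medians changed sign under library total scaling. The p53 and apoptosis list had a median of -0.03, the immediate early list -0.02 and the heat shock list 0.02, all inside the range of random lists, and the last 2 changed sign with the scaling. Polycomb and DNA methylation genes had a median of 0.04. Replication-dependent histones had 3 of 30 members measured and a median of -0.16. Ribosomal protein genes had a median of 0.09, with 9660 of 10000 random medians below. Nuclear-encoded respiratory chain genes were at -0.03, and mitochondrially encoded genes at -0.09, with 3 of 10000 random medians below. Mitochondrial transcripts made up 2.61% of control reads and 2.43% of knockout reads.

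**Figure D3:**
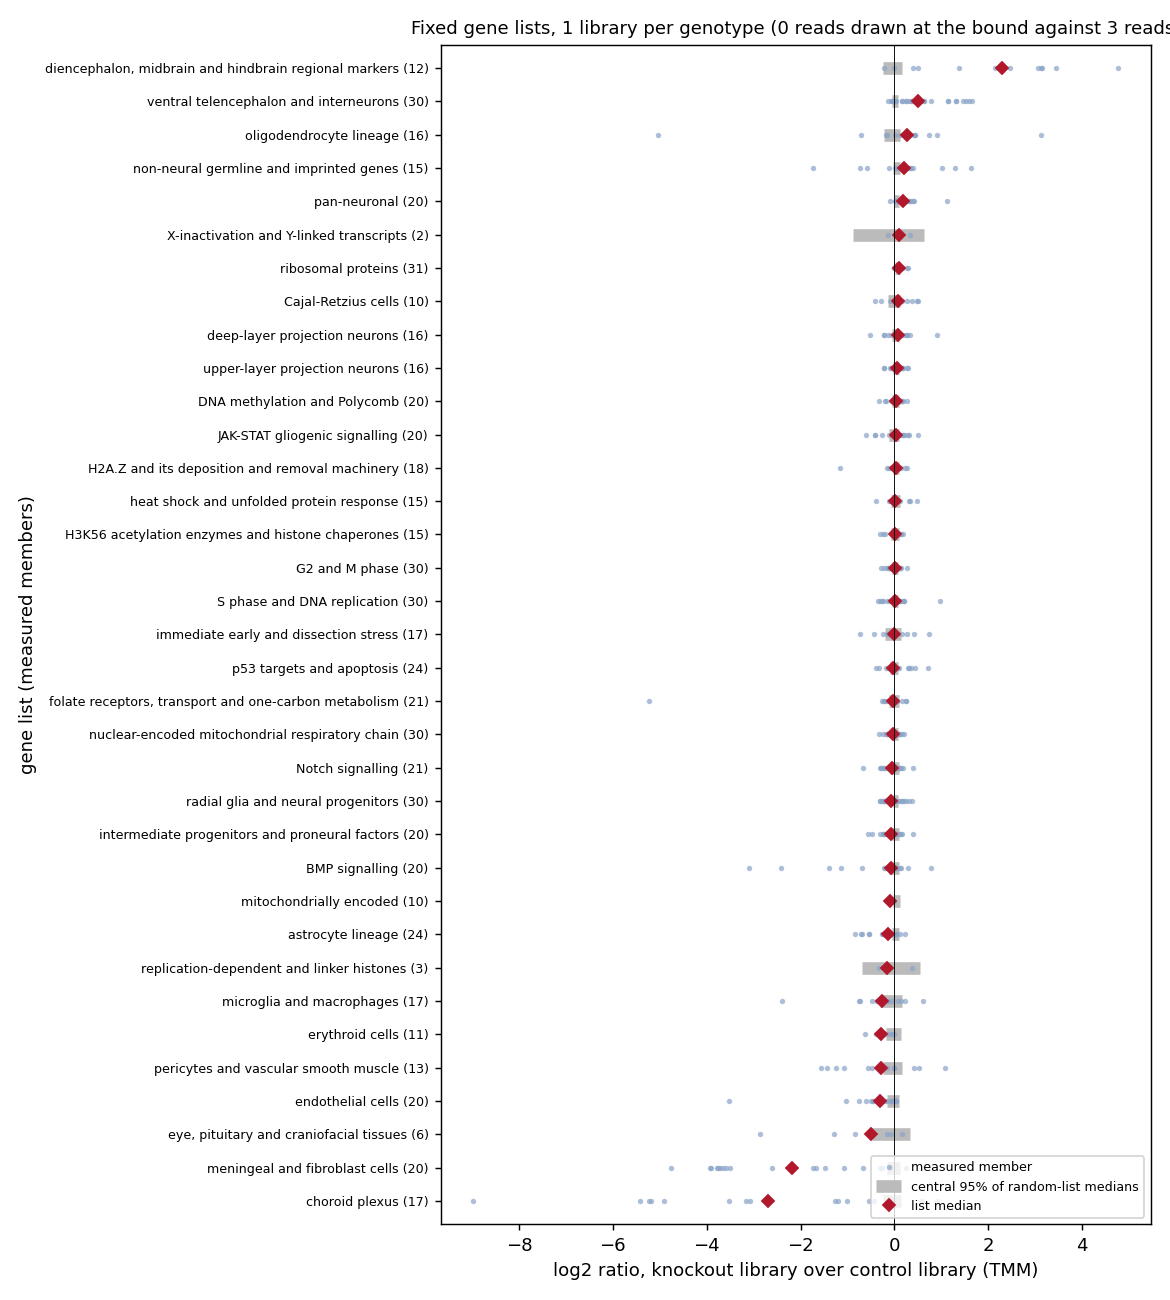
Log2 ratio (knockout over control library, x axis) of the measured members of each of the 35 fixed lists (rows, number measured in brackets), with the list median and the central 95% of medians of 10000 expression-matched random lists. The choroid plexus median lies at -2.69, the meningeal median at -2.18 and the diencephalic median at 2.30.

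Annotation terms carried by the deposited table were ranked by their medians. Among 1492 terms with 15 to 200 measured genes, the 5 lowest medians belonged to collagen trimer (-0.54, 18 of 40 genes at least 1.5-fold lower), scavenger receptor activity (-0.50), structural constituents of the extracellular matrix (-0.34), basal plasma membrane (-0.30) and extracellular matrix (-0.30). The 5 highest belonged to anatomical structure formation in morphogenesis (0.35, 6 of 16 genes higher), glutamate-gated ion channels (0.32), GABA signalling (0.26), eating behavior (0.26) and glutamatergic transmission (0.22).

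The authors' deposited table marks 318 genes as significant, 231 higher in the control and 87 higher in the knockout. The test behind the adjusted p-values of the authors' deposited table is not given in the sources used here, and with 1 count column per genotype they are read here as a comparison of the 2 libraries, not of the genotypes. Of the 231 genes that the authors' deposited table marks as higher in the control, 36 are on lists of other tissues, 13 of them on the choroid plexus list and 14 on the meningeal list. Of the 87 marked as higher in the knockout, 16 are on the 2 regional lists. In the authors' deposited table Folr1 is 57.5-fold higher in the control (adjusted p = 1.48e-12) and H2afz is 2.29-fold higher in the control (adjusted p = 1.33e-57). The authors' deposited table gives Gfap and Stat3 adjusted p-values of 0.583 and 0.434. Of the 318 marked genes, 261 were measured here.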

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

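The alternatives without genes on the other-tissue and regional lists, and the reduced astrocyte list, were chosen after seeing the data; all others were planned. Numbers of genes apart depended on the read minimum and fold threshold. At least 1.5-fold higher and lower were 1833 and 2270 genes with a minimum of 1 read, and 165 and 200 with a minimum of 100 reads, where all were beyond counting error. With a fold threshold of 2 they were 138 and 289, of which 116 and 236 were beyond counting error. Without the genes on other-tissue and regional lists they were 483 and 738. The authors' deposited table has 802 genes higher in the control and 662 higher in the knockout at its adjusted p threshold, and 231 and 87 with the 2-fold limit added. The log2 ratio of H2afz stayed within its counting interval under every scaling and prior tried.

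With a minimum of 100 reads the list medians were -1.199 for choroid plexus, 0.49 for the diencephalic list and -0.0058 for pericytes. The eye and craniofacial median turned to 0.0405, whereas the meningeal median moved further from 0, to -2.62. This minimum leaves out the members with few reads, so these medians cover other genes than the main ones. As means, the lists gave -0.0325 (H2A.Z machinery), -0.28 (folate), -0.20 (astrocyte), -0.41 (BMP), 0.23 (pan-neuronal), 0.59 (ventral), 0.0731 (oligodendrocyte), -0.60 (endothelial) and -1.28 (eye and craniofacial), where single extreme members weigh more. The meningeal median was -1.74 without its most extreme member, and the astrocyte median was -0.0817 without Cd44, Clu, Id3, Apoe and Gja1, which were its 5 lowest members, so that a smaller size was fixed by the choice; it still lay below the random range (-0.04 to 0.10), with 9 of 10000 random medians lower. Scaling by library total, with and without the 50 most-read genes, gave 0.14 and 0.14 for pan-neuronal, 0.0571 and 0.0584 for ribosomal, and -0.12 and -0.12 for mitochondrially encoded genes, the last at -0.0659 by median of ratios. For list medians, 224 alternative values stayed within counting error, some of them with a change of sign in lists near 0. The number of lists outside the central 95% of random lists was 15 and ranged from 12 to 15. All 5 terms at each end were the same under library total scaling. That scaling moves every log2 ratio by nearly the same amount, so the ranking could hardly change. No paired analysis was possible because each genotype has 1 library. Depth limits genes such as Gfap, with 14 reads in all, to no detectable difference.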

Other observations

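Imprinted genes stood apart in both directions. Igf2, a growth factor gene expressed in choroid plexus and meninges, had 1284 reads in the control library and 399 in the knockout library, 3.34-fold lower (2.99 to 3.75). Dlk1 had 143 and 463 reads, 3.11-fold higher (2.58 to 3.78), and Peg10, a retrotransposon-derived imprinted gene, was 2.03-fold higher (1.89 to 2.18). The list of imprinted and germline genes had a median log2 ratio of 0.21, with 3 of 15 measured members at least 1.5-fold higher and 3 lower. Xist, the RNA of X inactivation, had 22095 and 20857 reads, and Kdm5d, a Y-linked demethylase gene, 16 and 21, so that each library held transcripts of both kinds. The list of sex-linked transcripts had 2 members measured and a median of 0.09.

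In the paragraphs that follow, the medians of 2 held-out lists, written after the patterns were seen but before the values of their genes were looked at, were chosen before the result; all other tests were chosen only after it, and the test of neuronal genes at large replaced 2 tests of the highest pan-neuronal member, 1 of which left that explanation open.

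Choroid plexus and meningeal genes, Folr1 included, were lower in the knockout library. The lower values were not confined to Folr1. The other 16 measured choroid plexus genes had a median log2 ratio of -1.98, outside the random range of -0.23 to 0.13. That list is the pattern itself, so this value describes the pattern and is no separate test of Folr1. Less choroid plexus in the tissue of the knockout library may account for the choroid plexus part of this pattern. Of 15 held-out choroid plexus genes, 8 were measured. Their median was -1.12 (counting interval -1.73 to -0.55), and 5 of the 8 were at least 1.5-fold lower. No meningeal genes were held out, so less meninges was not tested in this way. The most abundant held-out genes, Igfbp2 and Slc29a4, which cortical tissue could also express, were at -0.26 and 0.08. These values do not show whether choroid plexus and meningeal cells were missing or were present with lower expression of these genes. If tissue was missing, 1 library per genotype cannot tell whether it was left out at dissection or failed to form in the knockout embryos. The meningeal median in the knockout library was -2.18.

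Diencephalic and ventral telencephalic genes were higher in the knockout library. In these 2 libraries the rise of neuronal genes at large was smaller, with a pan-neuronal median of 0.18 (counting interval 0.15 to 0.21). The ventral list was at 0.49 (0.41 to 0.56) and the diencephalic list at 2.30 (1.58 to 2.96). The 5 diencephalic members with at least 100 reads were at 0.49 (0.25 to 0.72). A single pan-neuronal member, Nefl at 1.115, lay above 0.49. The intervals cover counting error only, not the spread among genes or between libraries. The comparison was also chosen after its values were seen, so it does not decide whether a general neuronal rise was the whole cause. More diencephalic tissue in the knockout library was tested with 15 held-out thalamic and hypothalamic genes, and this prediction failed: the 4 measured genes had a median of -0.15 (counting interval -0.28 to 0.07), below the 1.5-fold required, while ventral tissue was not covered. By a criterion set after that result, the test was read as not excluding added tissue either. Slc17a6, Lef1 and Fezf1 had 672, 147 and 104 control reads against a median of 18 for the listed genes, where a small share could be hidden. Tcf7l2, however, had 111 control reads and 1017 in the knockout library. A control level like that of Fezf1 thus did not hide the rise of Tcf7l2. Tcf7l2 is 1 gene with a large rise, so it does not show whether smaller rises of the held-out genes were hidden. The criterion, set after the result, still carries little weight. Trh, a hypothalamic hormone gene with 8 and 25 reads, was at 1.531, so the held-out genes went both ways. Added tissue and expression of regional genes in cortical cells of the knockout cannot be told apart here.

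Raly and Eif2s2 were lower and agouti locus reads higher in the knockout library. A candidate explanation is a deletion allele of the lethal yellow kind, in which the segment from Raly through Eif2s2 is lost from a single chromosome copy and agouti is transcribed from the Raly promoter. The summed reads of Raly and Eif2s2 had a log2 ratio of -0.94 (-1.04 to -0.85), 52.0% of the control level (48.7 to 55.6). Any pooling of embryos is not given, and in a pool this level would need the allele in nearly all knockout embryos. Reads assigned to agouti were found in the knockout library alone, but Gm14226, within the agouti span, had 14 control and 817 knockout reads. The other 31 measured genes within 1 Mb had a median of -0.085, but 3 were at least 1.5-fold lower, of which Cdk5rap1 and Necab3 were beyond counting error and are not part of such a deletion. Regulation of this locus by H2A.Z cannot be told apart from such an allele with 1 library per genotype, and no genotype at agouti is given in the sources used here.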
